A study of Mus musculus with 3 samples.

How the data were processed

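The deposited count table holds UMI counts per gene and cell that, per the labels, the authors made from 10X Chromium 3' v2 libraries with Cell Ranger (version not given) on mm10. A table of natural log values was also deposited, which per the labels the authors made with Seurat 2.3.4. Its values equalled ln(1 + 10000 × count / the cell's total) of the counts to within 5.00e-07, for 13511 of the cells (54.7%). Every result below came from the counts. How the authors chose the 13511 cells is not stated, and those cells served as an alternative.

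Cells with at least 500 genes and at most 20% mitochondrial UMIs were kept, which left 24672 and removed 23. The lowest total was 3538 UMIs. Scrublet, run per run in scanpy, called 0.104%, 0.114% and 0.110% of the cells of runs 1, 2 and 3 doublets, too few for the cells loaded, so the doublet call was taken not to have worked and doublets were kept. Barcodes shared between pairs of runs numbered 83 to 108. Counts were scaled and logged, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 with seed 1 gave 23 clusters (scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15). A cluster took the name of another cell type when at least 3 markers of 1 type alone reached 50 CPM and 4 times the level in the other cells (10 CPM added to both), and its median Müller marker ratio to other cells was at most 0.5. Clusters with no such type and at least 5 Müller markers at 100 CPM were named Müller glia-like. A cluster stayed unnamed when it passed for more than 1 type, when its Müller ratio was above 0.5, or when its 10 leading genes held more markers of another type. These naming limits were set after the data were seen. Names end in "like" because they rest on transcripts alone.

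Cells were thinned at random to 1000 UMIs before classes were set, so that depth would not set them. Cycle-high cells had at least 2 UMIs of the 56 listed G2/M genes in the table, and cycle-low cells had 0 of these and of the 40 listed S phase genes. YAP-target-high and YAP-target-low cells were set by the quartile limits of the UMIs of the 9 listed YAP targets among cycle-low cells of each run. Because UMIs are whole numbers with many ties, the limits were at least 3 in every run for the high class and 0 in run 1 and at most 1 in runs 2 and 3 for the low class. The classes therefore held more than the quartiles and were not set alike in the runs. The classes, the gene lists, these 2 comparisons and their alternatives were chosen before the data were examined. The comparisons with 6 targets, in cells thinned to 3500 UMIs with at least 4 against 0, and the leaving out of Spc25 were chosen after the data were seen. In both gene comparisons with these targets, Spc25 was not counted when cycle-high and cycle-low cells were set. The cycle-high class held 6996 cells (2119 to 2641 per run, median UMIs 13985 to 18154) and the cycle-low class 7403 (1688 to 2908, median UMIs 8686 to 10554). The planned YAP classes held 2292 and 3053 cells. Over single cells of the cycle-high and cycle-low classes the medians were 456 and 1329 CPM for Glul, 1153 and 5612 CPM for Apoe, and 0 and 0 for C1qa.

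Counts were summed over the cells of each class and run, giving 3 pairs of profiles. Genes were filtered with filterByExpr, scaled by TMM and tested with edgeR 4.0.16 quasi-likelihood with the run as a block (R 4.3.3), with an adjusted p under 0.05 as the threshold. Genes that define the classes were left out of the tests after scaling. Changes are log2 of high over low, and the SE is the absolute change divided by the square root of the F statistic. Gene lists were tested with camera (limma 3.58.1) on log2 CPM with prior count 2, at a preset correlation of 0.01, with an estimated correlation and with fry, which tests whether genes move on balance one way. DESeq2 1.42.0 served as the other tool. Named genes were, in each comparison, the 10 largest rises and the 10 largest falls among called genes with a change of at least 1, a mean of at least 50 CPM and the same direction in every run. Class-defining, ribosomal, mitochondrial and unnamed predicted genes were left out. To these were added up to 4 called genes per list by level and 8 genes fixed before the data were examined. Positions are from GENCODE M21. The method was tested on simulated data with 200 changed genes per comparison. It recovered 91%, 83%, 73% and 77% of 2-fold and 83%, 68%, 46% and 45% of 1.5-fold changes in the cycle, planned YAP, 6-target and within-YAP comparisons, with 4.40%, 5.03%, 4.80% and 0.813% of calls false. Every simulated gene of a comparison had the same dispersion, and both classes of a run shared its run effects. The real data differ, with most tested genes called in the cycle comparison, so these rates need not carry over.

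The alternatives were other size factors, no low-count filter, DESeq2, no run block, each run left out, 2000 UMIs, Scrublet doublets out, a mitochondrial limit of 10%, the authors' cells, at least 4 cycle UMIs, an S phase class, other YAP selections, other list tests, other clustering resolutions and other gene limits. Added after the data were seen were Spc25 left out, the highest 5% of doublet scores left out and unnamed clusters with Müller markers included. Values of 3 genes, and the tests that needed them, are not reported here.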

Results

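The series measured single-cell RNA from the retinas of adult mice in which tamoxifen switches on Yap5SA, a YAP protein that the Hippo kinases cannot restrain, in cells that express Glast. The retinas were injured with N-methyl-D-aspartate (NMDA), which kills retinal neurons, and 2 days later tdTomato-positive cells were sorted and loaded on 10X Chromium droplets. All 3 runs belong to the same group, and the labels hold no control group, no uninjured retina and no retina without Yap5SA. The comparisons therefore set classes of cells within each run against each other. The deposited count table held 24695 cells, with 7670 cells in run 1, 8802 in run 2 and 8223 in run 3. Total counts were 94858762, 122888236 and 97032672 unique molecular identifiers (UMIs), and the median cell held 9664, 11200.5 and 9407 UMIs. The labels call the 3 libraries runs and do not say that they are separate animals. The edgeR and DESeq2 fits took out the level of each run, except where the run block was left out. Their p-values below therefore rest on how class differences varied over the 3 run pairs, and that variation may be partly technical. Those of camera compare the genes of a list with the other genes. With the preset correlation they rest on an assumed value and do not measure the spread between runs.

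Cells that carried the markers of Müller glia, the main glia of the retina, made up 89.8% ± 11.1 (SD, n = 3 runs) of the cells. They formed 16 of 23 clusters and held 22250 cells. Astrocyte-like cells formed 1 cluster and 1.03% ± 0.0842 of the cells (SD, n = 3), and microglia-like cells formed 1 cluster and 0.319% ± 0.228 (SD, n = 3), or 0.192% without run 1. No cluster was named as rod-, cone-, bipolar-, amacrine-, ganglion-, horizontal-, endothelial-, pericyte-, RPE-, oligodendrocyte-, lens-, erythrocyte-, neutrophil- or T cell-like. Another 5 clusters stayed unnamed and held 21.5% of the cells of run 1, 2.89% of run 2 and a smaller share of run 3 (mean 8.90% ± 10.9, SD, n = 3). The largest of them, cluster 9, had 1305 cells, of which 99.9% came from run 1. Its cells carried Glul at 3544 CPM, a count scaled to a common total, and Rlbp1 at 1722 CPM, above the 1152 and 1015 CPM of Müller glia-like cells. It stayed unnamed because the transthyretin gene Ttr, also a marker of retinal pigment epithelium, was among its leading genes.

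Among genes that code neither ribosomal nor mitochondrial proteins, the highest levels in Müller glia-like cells were those of Malat1, Eef1a1, S100a6, Mt1, Ftl1, Apoe, Dbi, Actb, Crym, Vim, Fth1, Clu, Cryab, Mt2 and Gpx4. They ran from 30779 CPM for Malat1 to 2753 CPM for Gpx4. Apoe, a glial lipid carrier, stood at 4484 ± 319 CPM, and the intermediate filament gene Vim at 3596 ± 318 CPM (SD, n = 3). The endogenous Yap1 gene stood at 25.2 ± 2.22 CPM (SD, n = 3). The table had no entry for the transgene or for tdTomato, so recombined cells could not be told from others by the transgene itself.

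Retinal progenitor and neurogenic transcripts were read as levels, since no control group exists to compare them with. Of the 36 listed genes in the table, 11 stood at 50 CPM or above in Müller glia-like cells, among them Sox2 (205 ± 15.9 CPM), Pax6 (294 ± 21.2 CPM) and Rax (261 ± 5.59 CPM; SD, n = 3), transcription factors that progenitors and adult Müller glia share. Dll4 had 0 UMIs, which at this depth allows up to 0.0104 CPM, and Lin28a had 10. Neurog2, a proneural factor, stood at 8.31 ± 2.61 CPM (SD, n = 3) and at 36.9 CPM in cluster 8. After each cell was thinned to 1000 UMIs, 0.976% ± 0.340 of Müller glia-like cells held a Neurog2 UMI, against 0.166% ± 0.202 of astrocyte-like cells, taken as background in place of rods. In unthinned cells, which differ in depth, the shares were 7.62% ± 1.77 and 2.57% ± 2.71. The thinned share exceeded that of astrocyte-like cells in every run for 25 of the 36 genes. Rod transcripts, in UMIs per cell, were also higher in Müller glia-like than in astrocyte-like cells, with a median ratio of 5.76. Astrocyte-like cells therefore did not measure the background of Müller glia-like cells. The comparison cannot tell Neurog2 made in these cells from RNA carried over from other cells.

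The 56 listed genes of the G2 and M phases were counted in cells thinned to 1000 UMIs, and cells with at least 2 such UMIs were called cycle-high. They made up 31.8% ± 3.85 of Müller glia-like cells, against 11.9% ± 2.37 of astrocyte-like and 37.1% ± 10.7 of microglia-like cells (SD, n = 3 runs). The last 2 shares rested on few cells, 30 of 253 astrocyte-like and 25 of 77 microglia-like cells. Spc25, a kinetochore gene of that list, was carried at 654 CPM by cluster 2, where the other listed genes together held 167 CPM. Without Spc25, which was left out after its levels were seen, the share was 23.0% ± 1.84 of Müller glia-like cells (SD, n = 3) and 10.6% of astrocyte-like cells. With at least 4 UMIs it was 19.2% ± 1.36. Of the Müller glia-like cells, 5200 lay at 1 UMI and 1916 at 2 UMIs, next to the limit.

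Cycling Müller glia-like cells lay mostly in clusters that also carried YAP target transcripts. The listed genes were not left out of the clustering, and cycle genes led several clusters. That cycle-high cells gathered in few clusters was therefore partly built in. The following split was made after the levels were seen: 6 of the 16 Müller glia-like clusters (3, 5, 10, 13, 16 and 19) carried Igfbp2, which binds insulin-like growth factors, at 1914 CPM or more, and in the other 10 it was at most 58.4 CPM. These 6 clusters held 31.5% ± 4.77 of Müller glia-like cells and 70.7% ± 2.43 of the cycle-high cells, or 94.7% ± 0.842 of those called without Spc25 (SD, n = 3). Without Spc25, 69.6% ± 5.45 of the cells inside them were cycle-high and 1.78% ± 0.375 of those outside. With Spc25 counted, clusters outside them also held cycle-high cells, up to 20.5% in cluster 2. Amotl2 stood at 276 ± 47.8 against 37.1 ± 14.9 CPM and Lats2 at 82.1 ± 10.9 against 9.79 ± 0.793 CPM. Ccnd1, the gene of cyclin D1, stood at 1116 ± 49.4 against 202 ± 34.9 CPM (SD, n = 3). Cyr61 (Ccn1), also a YAP target, stood at 1343 ± 195 inside and 1539 ± 359 CPM outside them, and Yap1 at 21.8 ± 1.82 and 28.6 ± 1.97 CPM. Cluster 13 was the member of the group with few cycle transcripts. It carried Igfbp2 at 3146 CPM and Ccnd1 at 1066 CPM, with Mki67 at 4.51, Top2a at 5.62 and Mcm5 at 13.7 CPM. It also carried Cdkn1c, the gene of the cell cycle inhibitor p57, at 331 CPM, against 84.4 CPM or less in the other 5 clusters. Cdkn1a, the gene of the inhibitor p21, went the other way, at 14.1 CPM in cluster 13 and 38.9 to 123 CPM in the other 5.

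**Figure D1:**
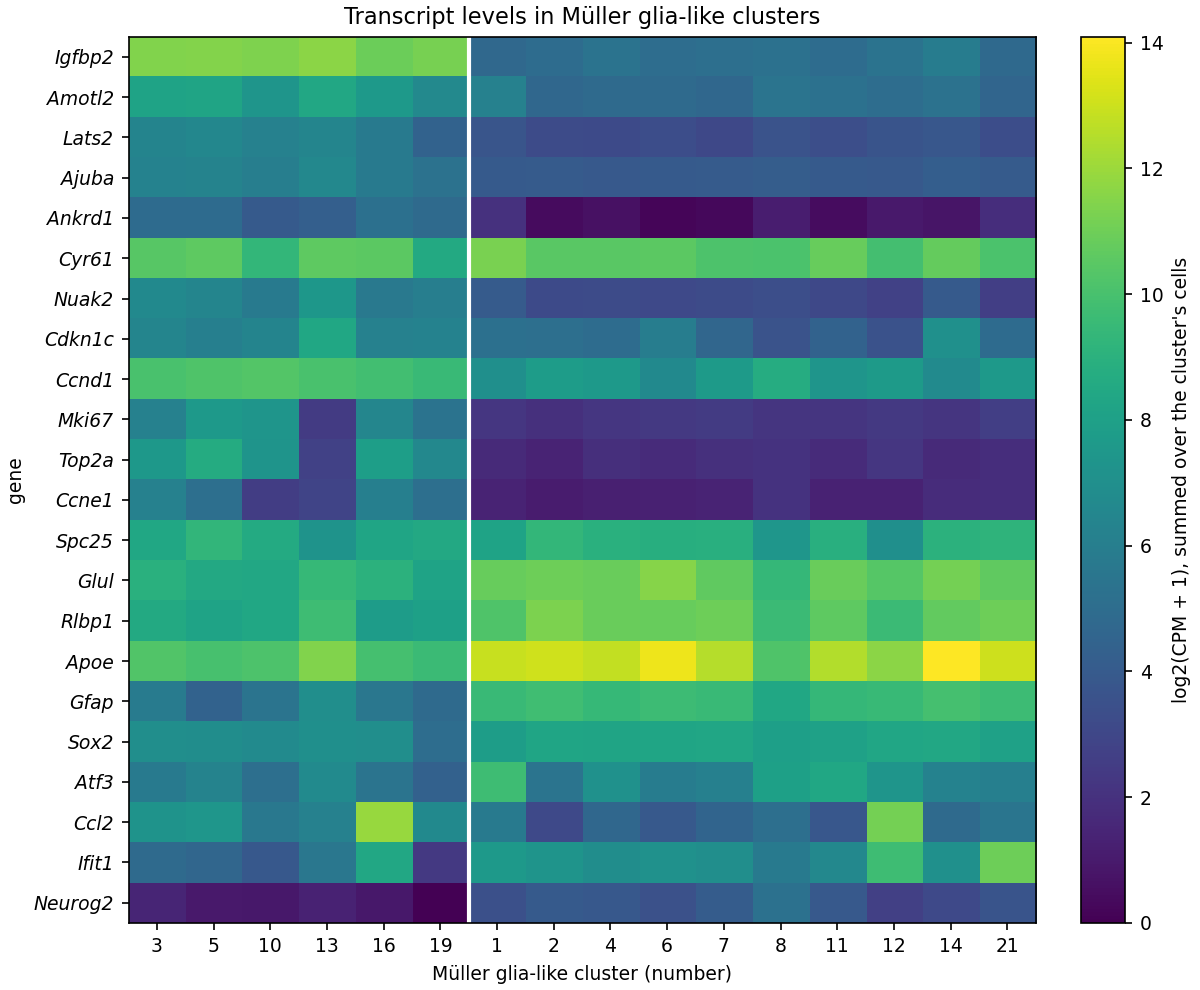
Levels of selected genes (rows, chosen after their values were seen) in the 16 Müller glia-like clusters (columns), as log2(CPM + 1) of counts summed over each cluster's cells. The 6 clusters left of the white line carried Igfbp2 at 1914 CPM or more. Of these, cluster 13 carried little Mki67 (4.51 CPM) and Top2a (5.62 CPM).

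Cycle-high Müller glia-like cells were first compared with cycle-low cells of the same runs, which had no UMI of the G2/M or S phase lists. This asks what accompanies division in these cells. The Müller identity genes fell as a group: of 27 measured, 24 fell, 2 rose and 1 did not pass, with a median log2 change of -1.14 (camera adjusted p = 0.531 with an estimated correlation). Cycle-high cells held 1.75 times the UMIs of cycle-low cells, and in UMIs per cell the list changed by -0.32. Rlbp1, the retinaldehyde-binding protein of Müller glia, changed by -1.28 ± 0.06 on the log2 scale, Glul, glutamine synthetase, by -1.16 ± 0.08, Apoe by -1.49 ± 0.08, Dbi by -1.18 ± 0.09 and Crym by -1.52 ± 0.08 (SE, 3 run pairs). G1 regulators rose, with 15 of 20 higher and 2 lower and a median of 1.56. Among them Ccnd1 rose by 1.57 ± 0.11, Ccnd2 by 2.40 ± 0.14 and the cyclin D kinase gene Cdk4 by 1.35 ± 0.06. The fall of glial transcripts spared Vim, which rose by 0.45 ± 0.06, and S100a6, which rose by 0.79 ± 0.06, while the reactive glia gene Gfap fell by 2.17 on the log2 scale (SE 0.13). The sizes depended on how cycle-high cells were defined: over the alternatives Gfap ran from -3.90 to -1.35, Apoe from -2.43 to -0.94 and Rlbp1 from -2.10 to -0.80. Gfap lies on chromosome 11 at 102887336 to 102900912 and Ccnd1 on chromosome 7 at 144929931 to 144939925 (mm10).

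Other gene groups moved with them. Their changes are shares of RNA, and cycle-high cells held more UMIs per cell, so the smaller falls need not be falls per cell. UMIs per cell were not computed for these groups. Genes of the cytoskeleton and extracellular matrix rose, 20 of 25 with a median of 0.72, as in Actb (0.55 ± 0.05) and Myl12a (0.92 ± 0.05). The 9 YAP targets of the selection list were tested here as well, a choice made later: 7 rose and 1 fell, with a median of 1.31. Hippo pathway components rose in 10 of 18 cases and fell in 3. The YAP partner Tead1, named for its level, rose by 1.06 ± 0.06, while Wwtr1, the gene of the YAP relative TAZ, changed by -0.33 ± 0.08 and Yap1 by -0.34 ± 0.06. Wwtr1 did not pass without run 2 (-0.21, edgeR adjusted p = 0.0844), and the Yap1 change was absent with the S phase class (-0.00300, edgeR adjusted p = 0.990). Immediate early and stress genes fell, 15 of 19, as in Fos (-1.16 ± 0.06), Jun (-0.98 ± 0.06) and Junb (-1.63 ± 0.08). Interferon response genes fell in 16 of 17 cases, with Ifit3 at -1.42 ± 0.10 and Isg15 at -0.75 ± 0.06, and Bst2 the exception at 0.39 ± 0.06. Retinal progenitor genes fell in 12 of 16 cases (Rax -1.33 ± 0.07, Hes1 -1.21 ± 0.06, Sox2 -0.87 ± 0.06), with Lhx2 higher by 0.43 ± 0.05. Neurogenic genes fell in 10 of 13 cases (Btg2 -1.52 ± 0.10, Hes6 -1.01 ± 0.07, Sox4 -0.86 ± 0.05). Notch pathway genes fell in 7 of 11 cases (Hes5 -1.91 ± 0.16, Notch1 -0.66 ± 0.07), and genes tied to glial quiescence in 9 of 12 (Btg1 -0.89 ± 0.07, Zbtb20 -0.26 ± 0.05). Rod transcripts fell in 10 of 10 cases (Gngt1 -0.74 ± 0.12; fry adjusted p = 0.0867), beside the falls in the other neural and glial groups.

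The highest log2 changes were those of Tk1 (thymidine kinase, 6.17 ± 0.11), Fam64a (6.08 ± 0.18), Knstrn (5.90 ± 0.10), Cenpm (5.23 ± 0.11), Asf1b (5.15 ± 0.08), Cks2 (5.02 ± 0.11), Tcf19 (4.70 ± 0.08), Lmnb1 (4.30 ± 0.08), Mad2l1 (4.22 ± 0.08) and Cenpw (4.10 ± 0.13). Most of these act in DNA replication or mitosis, the process that defines the classes. The lowest were Lcn2 (lipocalin 2, -2.80 ± 0.16), Prss56 (-2.40 ± 0.13), Gfap, Nupr1 (-2.11 ± 0.10), Dclk1 (-2.07 ± 0.11), Chchd10 (-1.97 ± 0.06), Cela1 (-1.92 ± 0.09), Cdh13 (-1.91 ± 0.11) and Arc (-1.87 ± 0.14). Every gene named by rule for this comparison passed, with the largest edgeR adjusted p at 0.0384 for Nfib. The inhibitor gene Cdkn1a, named here and below after its values were seen, rose by 0.55 ± 0.12, and Cdkn1c did not pass (-0.13 ± 0.09, edgeR adjusted p = 0.209). By that test 4979 genes were higher and 5427 lower in cycle-high cells, of 13969 tested.

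By camera with its preset correlation the adjusted p was 4.35e-05 for Müller identity, 8.86e-05 for cytoskeleton and matrix, 0.00131 for interferon, 0.00145 for G1 regulators and for immediate early genes, 0.0146 for retinal progenitor and Notch genes and for the 9 YAP targets. It was 0.0179 for neurogenic and rod genes, 0.0237 for glial quiescence and 0.0240 for Hippo components. None of these 12 calls held with an estimated correlation (adjusted p = 0.618 for rod genes and 0.531 for each of the other 11 with an estimated correlation). Reactive gliosis genes (6 rose and 14 fell of 21, camera adjusted p = 0.0537), glycolysis genes (3 rose and 10 fell of 18, 0.179) and the independent YAP target list (8 rose and 5 fell of 19, 0.393) did not pass as lists. Nor did cholesterol synthesis (8 rose and 7 fell of 18, 0.831), microglia transcripts (1 rose and 1 fell of 5, 0.798) and p53 and apoptosis genes (10 rose and 3 fell of 16, 0.0559). The median and the mean had opposite signs for the independent YAP targets (-0.01 and 0.36, test upward) and for cholesterol synthesis (-0.09 and 0.11, test upward). Counts adjusted over the list alone were the same except for G1 regulators (15 rose and 3 fell), microglia transcripts (1 rose and 0 fell) and p53 genes (11 rose and 3 fell).

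The planned YAP comparison asked whether cycle-low Müller glia-like cells differ in YAP activity, since recombination need not reach every sorted cell. It split cells by their UMIs of 9 YAP targets at 1000 UMIs, and 503 genes were higher and 158 lower in the upper class, of 12200 tested (edgeR). The classes differed most in absolute level in Cyr61, which stood at 2239 ± 336 against 975 ± 358 CPM (SD, n = 3), while Amotl2 stood at 135 against 46.1 CPM. Cyr61 is also an immediate early gene, and immediate early and stress genes rose in 15 of 19 cases: Fos by 0.51 ± 0.03, Jun by 0.50 ± 0.03, Junb by 0.69 ± 0.04 and Btg2 by 0.67 ± 0.06. With Cyr61 and Ctgf taken out of the selection list, these 4 changed by -0.22, -0.25, -0.33 and -0.33, so their direction rested on those selection genes. Genes with the highest changes were Igfbp2 (1.83 ± 0.15), the actin-binding protein gene Cnn2 (1.32 ± 0.13), Cdkn1c (1.21 ± 0.15), Anxa3 (1.20 ± 0.09), Tpm1 (1.15 ± 0.11), Maff (1.14 ± 0.10), Bex1 (1.10 ± 0.12) and Arvcf (1.00 ± 0.12), and no gene fell by 1 or more under the naming rule.

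Cytoskeleton and matrix genes rose in 12 of 24 cases and fell in 0 (Actb 0.30 ± 0.04, Sparc 0.37 ± 0.06). Independent YAP targets rose in 5 of 19 and fell in 1 (Nuak2 1.45 ± 0.12, Myof -0.40 ± 0.07), and Hippo components rose in 4 of 18 and fell in 1 (Vgll4 0.60 ± 0.07, Tead1 0.41 ± 0.08, Wwtr1 -0.37 ± 0.08). Rod transcripts rose in 5 of 10 (Pdc 0.35 ± 0.07), but without Cyr61 and Ctgf in the selection Pdc, Gngt1 and Gnat1 turned to -0.0818, -0.0569 and -0.0973. G1 regulators rose in 5 of 17 (Ccnd1 0.37 ± 0.06, Ccnd2 0.58 ± 0.13). Müller identity genes rose in 7 and fell in 2 of 27 (Apoe 0.23 ± 0.03, Glul 0.21 ± 0.05, Crym -0.29 ± 0.03), and Apoe and Glul turned to -0.35 and -0.31 without Cyr61 and Ctgf in the selection. Rlbp1 (-0.13 ± 0.04, adjusted p = 0.105), Yap1 (-0.07 ± 0.09, adjusted p = 0.742), Gfap (-0.03 ± 0.07, adjusted p = 0.880) and Vim (0.03 ± 0.04, adjusted p = 0.804) did not pass. Reactive gliosis genes (3 rose and 2 fell of 21; S100a6 0.39 ± 0.06, Socs3 0.64 ± 0.05), retinal progenitor genes (2 and 2 of 15; Hes1 0.41 ± 0.05, Sox2 -0.23 ± 0.06) and neurogenic genes (2 and 2 of 10; Gadd45g 0.85 ± 0.07, Neurog2 -0.74 ± 0.15) moved little as groups. The same held for glial quiescence (2 and 1 of 12; Klf4 0.48 ± 0.06), Notch (2 and 0 of 11; Hey2 0.32 ± 0.08) and glycolysis genes (1 and 2 of 18; Slc2a1 0.46 ± 0.08, Pkm -0.15 ± 0.04). Of these, Socs3, Hes1 and Klf4 turned to -0.23, -0.35 and -0.12 without Cyr61 and Ctgf. Cholesterol synthesis, interferon and p53 genes had 0 members past the edgeR threshold of 18, 17 and 15.

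The camera adjusted p was 6.23e-12 for immediate early genes, 1.81e-07 for cytoskeleton and matrix, 6.15e-06 for rod transcripts, 0.00421 for independent YAP targets and 0.0116 for Hippo components. Each call ended with an estimated correlation (adjusted p = 0.600 for Hippo components and 0.570 for the other 4 with an estimated correlation) and with fry (lowest adjusted p = 0.0802). The other 11 lists did not pass, with camera adjusted p from 0.171 to 0.883. Reactive gliosis (median -0.04, mean 0.01, test upward) and glycolysis (median -0.02, mean 0.02, test downward) had medians and means of opposite sign. Adjusted over the list alone, the members that rose and fell were 9 and 2 for independent YAP targets, 10 and 4 for Müller identity, 4 and 3 for reactive gliosis, 3 and 2 for neurogenic and 4 and 1 for glial quiescence genes. They were 6 and 0 for G1, 5 and 1 for Notch, 16 and 0 for immediate early, 0 and 2 for cholesterol, 16 and 1 for cytoskeleton and 9 and 0 for rod genes, and those of the other lists did not differ. Without the run as a block, edgeR called 0 genes in this comparison, with 630 at an unadjusted p under 0.05, and DESeq2 with the block called 245.

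A sharper comparison was added after the levels were seen. It used 6 YAP targets that Cyr61 does not outweigh (Amotl2, Ajuba, Lats2, Ankrd1, Ptpn14 and Axl), and set cycle-low cells with at least 4 of these UMIs among 3500 against cells with 0. The upper class held 348 cells, of which 74.1% came from cluster 13, and the lower 5706. Of the listed targets left out, Cyr61 stood at 1595 against 1513 CPM, Ctgf at 25.9 against 21.3 and Crim1 at 115 against 73.6. The upper class thus stood out for the 6 targets that selected it, and hardly for Cyr61. The class was selected for 0 G2/M and S phase UMIs in thinned cells, and in full counts Top2a still stood at 5.76 against 1.68 CPM. Wisp2 (Ccn5), of the same protein family as Cyr61, rose by 6.08 ± 0.21, Igfbp2 by 5.88 ± 0.18, Vgll3, a partner of TEAD factors, by 5.61 ± 0.16, and Cdkn1c by 3.25 ± 0.11, together with Ccnd1 at 2.48 ± 0.08 and Ccnd2 at 3.24 ± 0.09 (SE, 3 run pairs). Cdkn1a changed by -1.26 ± 0.15. Igfbp2 lies on chromosome 1 at 72824503 to 72852474 and Cdkn1c on chromosome 7 at 143458339 to 143461050 (mm10). The other highest changes were those of Tinagl1 (5.16 ± 0.17), Pdlim2 (5.11 ± 0.18), Anxa3 (4.86 ± 0.14), Cnn2 (4.74 ± 0.12), Tagln (4.71 ± 0.17), Arsi (4.34 ± 0.12) and Csf1 (4.32 ± 0.12). The lowest were Npy (-2.63 ± 0.20), Aldoc (-2.60 ± 0.08), Trf (-2.44 ± 0.08), Cdh13 (-2.37 ± 0.12), Cela1 (-2.33 ± 0.15), Ndp (-2.26 ± 0.13), Pik3ip1 (-2.21 ± 0.12), Dclk1 (-2.17 ± 0.14) and Gfap (-2.15 ± 0.09).

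By group, cytoskeleton and matrix genes rose in 21 of 24 cases (Actb 1.36 ± 0.06, Sparc 1.32 ± 0.06). Independent YAP targets rose in 13 of 19 with 2 lower (Nuak2 4.31 ± 0.10, F3 0.54 ± 0.08, Gadd45a -0.36 ± 0.08) and Hippo components in 10 of 18 with 2 lower (Tead1 1.83 ± 0.08, Vgll4 1.53 ± 0.08, Tead2 -0.44 ± 0.12). Müller identity genes fell in 18 of 27 cases and rose in 5 (Clu -1.91 ± 0.06, Glul -1.48 ± 0.06, Apoe -1.43 ± 0.05, Rlbp1 -1.22 ± 0.06). The upper class held 1.55 times the UMIs per cell, and in UMIs per cell the list changed by -0.23, with -0.04 in run 1, against its median of -0.80. Changes of the other lists are shares of RNA too, so their smaller falls need not be falls per cell. Retinal progenitor genes fell in 10 of 15 (Rax -1.41 ± 0.08, Hes1 -1.07 ± 0.12, Sox2 -1.03 ± 0.09) with Lhx2 higher by 1.07 ± 0.07. Immediate early genes fell in 13 of 19 and rose in 3 (Junb -1.26 ± 0.07, Fos -0.90 ± 0.08, Hspa8 0.89 ± 0.08). Interferon genes fell in 12 of 17 and rose in 2 (Ifit3 -0.70 ± 0.07, Bst2 1.13 ± 0.08), and glial quiescence genes fell in 8 of 12 (Nfix -1.13 ± 0.08, Btg1 -0.92 ± 0.07) against the rise of Cdkn1c. Rod transcripts fell in 8 of 10 (Sag -0.36 ± 0.11, Gngt1 -0.40 ± 0.10, Gnat1 -0.31 ± 0.10), but in the subset of cells that the authors processed Gngt1 and Gnat1 were instead higher by 0.49 and 0.56 and passed, and Sag was 0.32 and did not. Yap1 itself differed by 0.03 ± 0.14 (adjusted p = 0.893). Vim rose by 0.74 ± 0.06 and S100a6 by 1.82 ± 0.05 among reactive gliosis genes, of which 7 rose and 10 fell of 20. G1 regulators rose in 8 of 17 and fell in 4, neurogenic genes rose in 1 and fell in 4 of 10 (Gadd45g 0.95 ± 0.07, Btg2 -1.21 ± 0.07), and Notch genes rose in 2 and fell in 6 of 11 (Notch2 0.87 ± 0.10, Hes5 -2.55 ± 0.20). Cholesterol genes rose in 4 and fell in 2 of 18 (Mvk 0.81 ± 0.12, Insig1 -0.69 ± 0.17), glycolysis genes rose in 7 and fell in 7 of 18 (Pgam1 0.71 ± 0.07, Eno1 -0.96 ± 0.06), and p53 and apoptosis genes rose in 6 and fell in 4 of 14 (Bcl2l1 1.56 ± 0.08, Aen 1.25 ± 0.10).

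By edgeR 2932 genes were higher and 2764 lower, of 11908 tested. The targets and limits were chosen after the levels in the clusters were seen, and 74.1% of the upper class came from cluster 13. This was therefore largely a comparison of that cluster with others. Its calls and p-values, those of the independent YAP targets included, describe these classes and do not test a link to YAP. The camera adjusted p was 1.16e-08 for cytoskeleton and matrix, 0.00322 for Hippo components, 0.00337 for Müller identity and 0.00521 for independent YAP targets. It was 0.0272 for immediate early genes, 0.0333 for retinal progenitor genes and 0.0339 for glial quiescence, interferon and rod genes. None of the 9 calls held with an estimated correlation (adjusted p = 0.597 for immediate early and rod genes and 0.427 for the other 7 with an estimated correlation), and without run 2 the number was 5. The other 7 lists had camera adjusted p from 0.0593 for G1 regulators to 0.995 for glycolysis, whose median of -0.03 and mean of -0.02 stood against an upward test, as did the median of -0.07 and mean of -0.01 of p53 genes. Counts adjusted over the list alone were the same except for independent YAP targets (13 rose and 3 fell), reactive gliosis (7 rose and 11 fell) and glial quiescence (1 rose and 9 fell). Of the 11908 genes tested in this and the cycle comparison, 2230 were higher in both and 2347 lower in both. Both drew on partly the same cycle-low cells, so shared calls alone do not show a shared program.

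**Figure D2:**
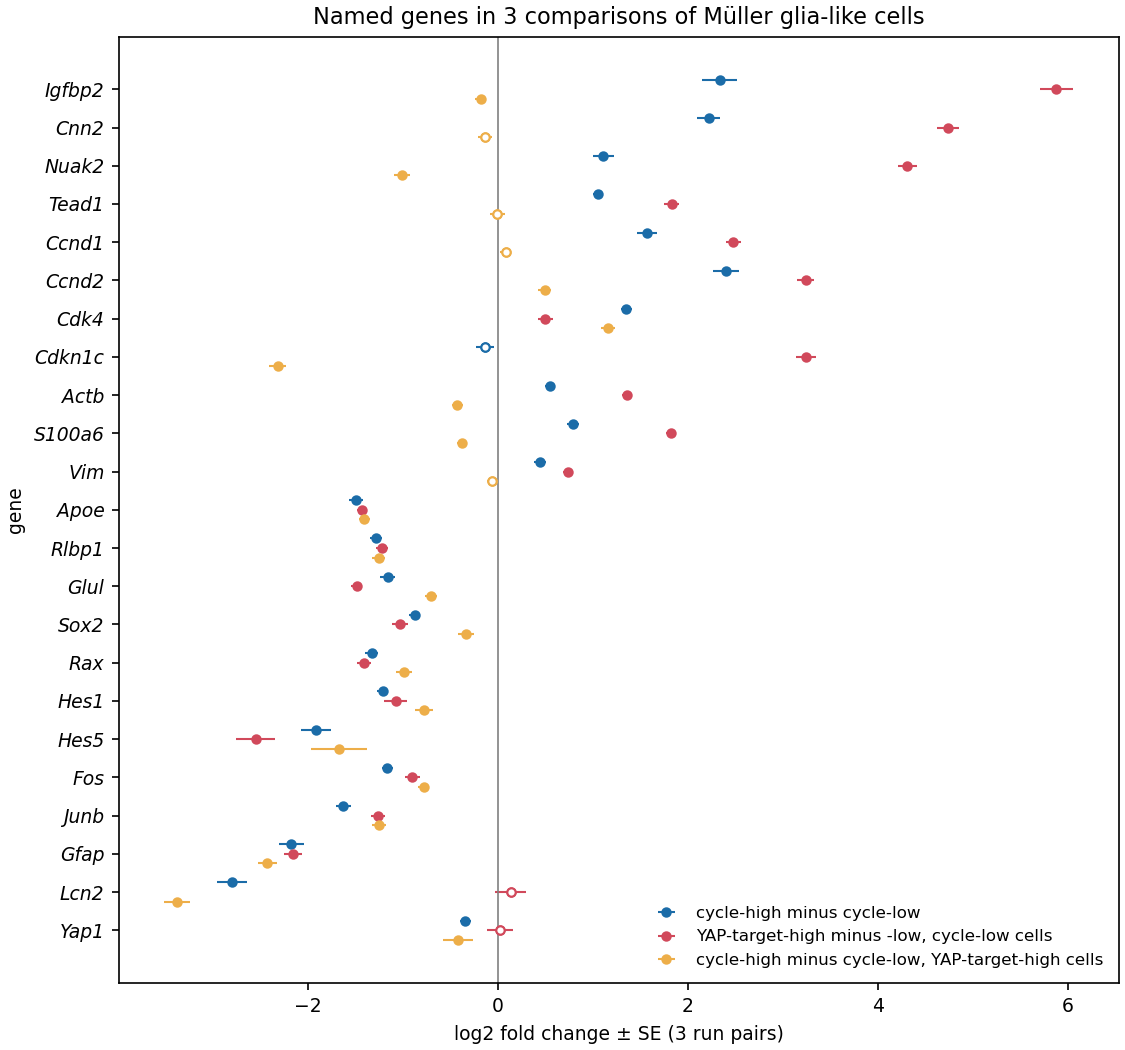
Log2 fold change (x axis) of named genes (y axis) in 3 comparisons of summed profiles, with bars for the SE over 3 run pairs and open circles where the edgeR adjusted p was 0.05 or more. Cdkn1c was 3.25 higher in YAP-target-high cycle-low cells and changed by -2.31 from these to YAP-target-high cycle-high cells, while Ccnd1 changed by 0.09 in that last step.

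The last comparison, also added, stayed within cells that had at least 4 UMIs of the 6 targets and set 1614 cycle-high against 348 cycle-low cells. Spc25 was again not counted for these classes. Of the cycle-low cells 74.1% lay in cluster 13, which held 0.972% of all cycle-high cells with Spc25 counted and 0.413% without it. This was therefore largely a comparison between clusters, and its calls and p-values describe these classes. The inhibitor gene Cdkn1c fell by 2.31 on the log2 scale (SE 0.09), while the inhibitor gene Cdkn1a rose by 1.95 ± 0.15. Ccnd1 differed by 0.09 ± 0.06 (adjusted p = 0.245), Ccnd2 rose by 0.49 ± 0.07 and Cdk4 by 1.16 ± 0.07. Müller identity genes fell in 26 of 27 cases with a median of -1.09, or by 0.40 in UMIs per cell (Rlbp1 -1.25 ± 0.06, Dbi -1.09 ± 0.06, Mt1 -1.08 ± 0.08, Glul -0.70 ± 0.06). Median UMIs over the runs were 21313 to 23370.5 in cycle-high and 13145 to 15467 in cycle-low cells. The smaller falls in the other groups, as in Sox2 and Btg1, therefore need not be falls per cell. Reactive gliosis genes fell in 13 of 20 cases and rose in 3 (Gfap -2.42 ± 0.10, Lgals3 -0.95 ± 0.08, Ccl2 0.48 ± 0.11), with Vim at -0.06 ± 0.05 (adjusted p = 0.411). Glycolysis genes fell in 8 of 18 (the glucose transporter gene Slc2a1 -1.66 ± 0.08, Aldoa -0.93 ± 0.06), immediate early genes in 16 of 19 (Junb -1.25 ± 0.07, Fos -0.78 ± 0.06), interferon genes in 16 of 17 (Isg15 -0.64 ± 0.10) and rod transcripts in 8 of 10 (Gngt1 -0.72 ± 0.11). G1 regulators rose in 11 of 20 and fell in 3, retinal progenitor genes rose in 2 and fell in 10 of 15 (Pax6 -0.64 ± 0.07, Sox2 -0.33 ± 0.08) and glial quiescence genes rose in 2 and fell in 8 of 12 (Btg1 -0.37 ± 0.09).

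The highest changes were again those of Tk1 (5.95 ± 0.20), Knstrn (5.68 ± 0.18), Asf1b (5.52 ± 0.22), Fam64a (5.50 ± 0.17), Cks2 (4.87 ± 0.11), Cenpm (4.71 ± 0.16), Incenp (4.55 ± 0.18), Mad2l1 (4.34 ± 0.16), Tcf19 (4.16 ± 0.15) and Lmnb1 (3.90 ± 0.13). The lowest were Lcn2 (-3.37 ± 0.13), Gfap, Hist1h2bc (-2.34 ± 0.08), Cdkn1c, S1pr3 (-2.05 ± 0.09), Mt3 (-1.99 ± 0.10), Hmox1 (-1.95 ± 0.11), Nupr1 (-1.86 ± 0.08), Mbd1 (-1.84 ± 0.10) and Trf (-1.82 ± 0.09). By edgeR 2536 genes were higher and 2696 lower, of 11392. The camera adjusted p was 6.38e-11 for Müller identity, 1.95e-04 for immediate early, 3.69e-04 for interferon, and 5.63e-04 for reactive gliosis genes. It was 0.00983 for G1, 0.0157 for glycolysis, 0.0213 for retinal progenitor, 0.0264 for rod and 0.0301 for glial quiescence genes. With an estimated correlation none of the 9 held (adjusted p = 0.257 for Müller identity and 0.349 to 0.629 for the other 8 with an estimated correlation). Independent YAP targets (2 rose and 10 fell of 19; Nuak2 -1.01 ± 0.09), Hippo components (4 and 4 of 18; Vgll4 -0.96 ± 0.08, Sav1 0.47 ± 0.12), and neurogenic genes (1 and 5 of 9; Sox4 -0.81 ± 0.09) did not pass as lists. Nor did Notch (1 and 4 of 10; Notch2 -0.62 ± 0.09), cholesterol (4 and 3 of 18; Sqle -0.73 ± 0.14), cytoskeleton (6 and 8 of 24; Tpm4 0.48 ± 0.07, Actb -0.42 ± 0.05) and p53 genes (7 and 2 of 15; Phlda3 0.80 ± 0.09, Trp53 0.65 ± 0.10), with camera adjusted p from 0.0638 to 0.833. Hippo components had a median of 0.02 and a mean of -0.04 with a downward test, and fry put the cytoskeleton list upward where camera put it downward. Adjusted over the list alone, 3 independent YAP targets rose and 10 fell, 14 reactive gliosis genes fell, 9 glial quiescence genes fell, 1 immediate early gene rose, 9 cytoskeleton genes fell and 8 p53 genes rose, with no other difference.

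**Figure D3:**
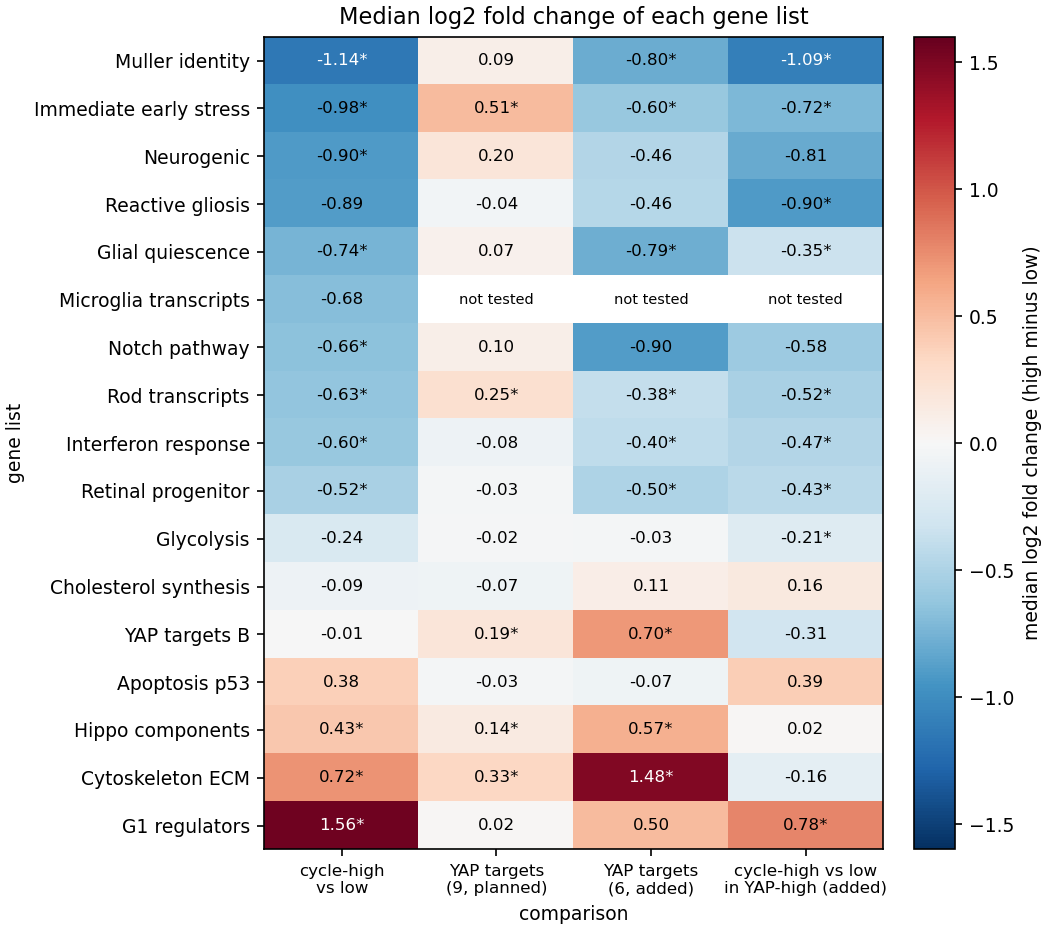
Median log2 fold change (colour and printed value) of each gene list (y axis) in the 4 comparisons (x axis), with an asterisk where the camera adjusted p with preset correlation was under 0.05. No asterisk remained with an estimated correlation, and Müller identity fell by 1.14 in cycle-high cells and by 0.80 in YAP-target-high cycle-low cells.

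Whether YAP target level goes with cycling was asked over all Müller glia-like cells. In the planned split by 9 targets, 35.8% ± 4.74 of YAP-target-high and 29.2% ± 3.29 of YAP-target-low cells were cycle-high, a difference of 6.62 ± 2.53 percentage points (SD, n = 3) that was positive in 3 of 3 runs. The exact two-sided permutation test of the paired differences gave p = 0.25, the smallest p that 3 runs allow. Without Cyr61 and Ctgf the shares were 45.8% and 25.2%, a difference of 20.6 ± 3.07 points. At 2000 UMIs the difference was 6.46 ± 5.82 points, with 7.65, 11.6 and 0.136 points in runs 1, 2 and 3. With the 6 targets, at least 4 against 0 in cells thinned to 3500 UMIs, it was 51.1 ± 6.15 points, where the list, the depth and the limits all differed from the planned split. With the 6 targets and without Spc25, 66.9% ± 3.84 of YAP-target-high and 6.07% ± 1.06 of YAP-target-low cells were cycle-high, a difference of 60.8 ± 4.09 points (SD, n = 3). The 6 targets and the removal of Spc25 were chosen after these levels were seen together in the clusters, so these 2 differences describe the cells and do not test the link.

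**Figure D4:**
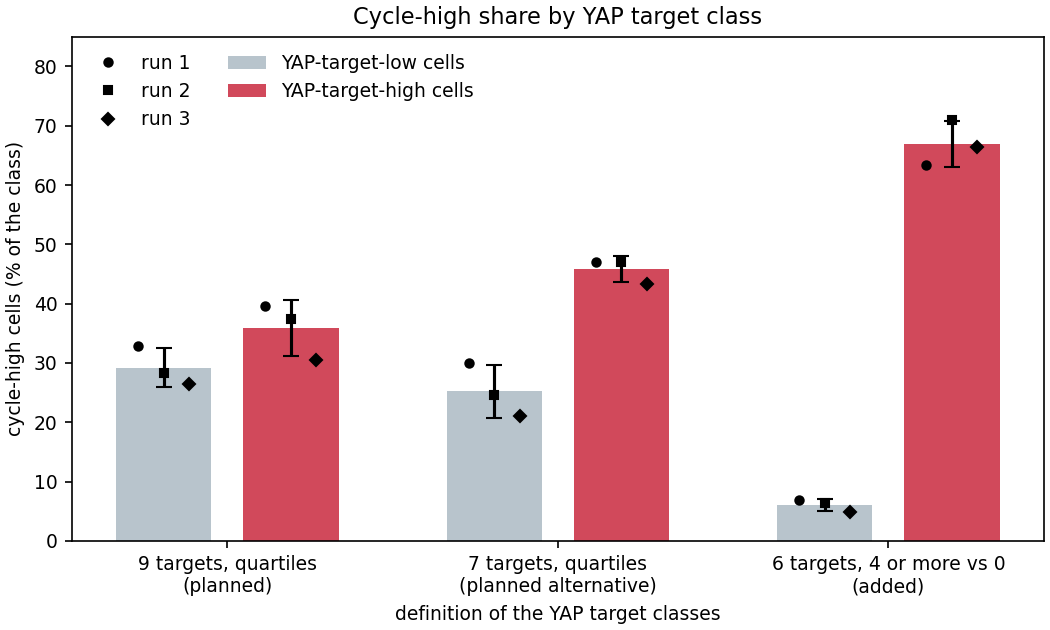
Share of cycle-high cells (y axis, %) among YAP-target-low and YAP-target-high Müller glia-like cells under 3 definitions of the classes (x axis), with bars for the mean, error bars for the SD and points for the 3 runs. The difference was 6.62, 20.6 and 60.8 percentage points from left to right.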

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

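The test for free RNA in this part was chosen only after the result was seen. Rod transcripts stood in Müller glia-like cells. Free RNA spread evenly over droplets would give alike UMIs per cell in every class, and the median ratio of Müller glia-like to astrocyte-like cells over the rod list was 5.76 (SD 2.52), which excludes an even spread as the whole source. That leaves the source of these transcripts open, and no biological explanation was tested, as there was no control group.

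The 5 unnamed clusters, described after their values were seen, differed in their leading genes. Cluster 9, almost all from run 1, led with Etnppl at 262 CPM. Cluster 15 led with the rod gene Gngt1 at 733 CPM and cluster 18 with the cone gene Pde6h at 2258 CPM, each beside Müller markers. Cluster 22 led with the bipolar cell gene Pcp2 at 1203 CPM and cluster 23 with the hemoglobin gene Hbb-bs at 6097 CPM.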

How the results depend on the processing

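Called genes numbered 5886 with an S phase class in the cycle comparison. In the planned YAP comparison they numbered 1049 without a low-count filter, 245 with DESeq2, 0 without the run block, 1081 in the authors' cells and 2589 without Ccn1 and Ccn2 in the selection. Within YAP-target-high cells DESeq2 called 3258. With an estimated correlation 0 lists passed in each of the 4 comparisons, and with fry 0 in the planned YAP comparison. In the 6-target comparison 6 lists passed without run 1, 5 without run 2 and 8 without run 3. The cycle-high share was 47.5% at 2000 UMIs, 90.1% unthinned, 19.2% with at least 4 UMIs, 23.0% without Spc25 and 36.8% in the authors' cells. Directions turned in the cycle comparison for F3 (0.0803), Nfib (-0.16) and Sqle (0.32) with the S phase class and Notch2 (-0.0511) in the authors' cells. In the planned YAP comparison they turned for Apoe (-0.0403) and Glul (-0.0214) in the authors' cells, and without Ccn1 and Ccn2 for Apoe (-0.35), Glul (-0.31), Lgals3 (0.19), Socs3 (-0.23), Hes1 (-0.35), Btg2 (-0.33), Klf4 (-0.12), Fos (-0.22), Jun (-0.25), Junb (-0.33), Gngt1 (-0.0569), Gnat1 (-0.10) and Pdc (-0.0818). In the 6-target comparison they turned in the authors' cells for Sag (0.32), Gngt1 (0.49) and Gnat1 (0.56). The cause was not tested. With each run left out the calls were 8789 to 10454, 570 to 670, 4594 to 5232 and 4349 to 4596, and the cycle-high share 29.8% to 33.6%. At Leiden resolution 2.0 the unnamed share was 18.0% and the Müller glia-like share 80.6%. A limit of 200 genes removed nothing, and Scrublet removed about 0.1% of cells.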

Other observations

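Some clusters, described after their values were seen, came mostly from 1 run. Cluster 1 (2791 cells) had 82.9% of its cells from run 3, and cluster 7 (1546 cells) had 90.9% from run 2. Clusters 12 and 16 held 1479 Müller glia-like cells, 1444 of them from run 2, with Ccl2 at 2905 CPM against 78.4 CPM in other Müller glia-like cells, Cxcl10 at 1479 against 33.7 CPM and Gbp2 at 940.5 against 40.1 CPM. Cluster 8, with 39.9% of its cells from run 1 and 52.9% from run 3, carried Neurog2 at 36.9 CPM and Hmga2 at 94.9 CPM. Ddx3y, on the Y chromosome, had 1216 UMIs in run 1, 0 in run 2 and 2324 in run 3, and Xist was found in 54.3%, 98.7% and 34.9% of Müller glia-like cells, so runs 1 and 3 held cells of both sexes and run 2 did not come from the same pool of animals.

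Of the tests of the lower Müller identity transcripts, dilution in cycle-high cells, also within YAP-target-high cells, and doublets with astrocytes were chosen only after the result was seen. Cycle-high cells held 1.75 times the UMIs of cycle-low cells, and per cell the identity list changed by -0.32 (SD 0.157), against the median of -1.14 as a share of RNA, so larger RNA content may account for most of the fall but not all of it. In the 6-target comparison the per-cell change was -0.23 (SD 0.170), with -0.04 in run 1, so dilution cannot be told from a fall there, while within YAP-target-high cells it was -0.40 (SD 0.0982) against -1.09, so dilution alone does not account for that fall. By the level of the cycle lists without Spc25, cycling cells left in the YAP-target-high cycle-low class would be 0.904% of it. That class was selected for 0 UMIs of the same lists in thinned cells, so a low share was set in advance. Cycling cells without these transcripts would not be seen either, so the value cannot exclude cycling cells. The median level of astrocyte or microglia markers in cycle-high cells reached at most 17.4% of the level in those types in any run. This leaves doublets open, and markers of rods, cones and bipolar cells were not part of the test. Astrocyte markers stood at 0.485 of their cycle-low level as a share of RNA. The larger RNA content of cycle-high cells alone lowers such a share, so the value does not decide on astrocyte doublets.

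Both tests of the chemokine clusters were chosen only after the result was seen. RNA from microglia could carry 0.00219% of the excess of Ccl2, since C1qa stood at 0.585 CPM there and 2991 CPM in microglia-like cells, which excludes that source. With 97.6% of these cells from 1 run, a difference between library preparations cannot be told from a difference between animals. No biological explanation was tested, as there was no control group.

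When the 6 profiles of each comparison were regrouped 3 against 3 in all 10 ways, 1 of 10 splits reached the real count in each comparison, the real split itself, with 10406, 661, 5696 and 5232 genes, and the highest other count was 0. With 10 splits no share under 0.05 can be reached.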
